A study of Mus musculus with 6 samples.

How the data were processed

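Messenger RNA levels were measured by bulk RNA sequencing in dorsal striatum of mice at postnatal day 21, in 3 homozygous knock-in and 3 wild-type samples, 1 library each. The sample titles give male animals, which the level of Xist described at the end calls into question. Per the labels' protocols, striatum was dissected into RNAlater, RNA was extracted with a miRNeasy kit, and libraries were prepared with a TruSeq kit. The deposited table gives 1 FPKM value, a level scaled for transcript length and library size, per gene and library, per the file headers. FastQC, HISAT2, SAMtools and StringTie are named in the submitters' processing notes, with no versions and no role for each. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. A label of the libraries names a stranded run. All 6 columns were assigned to samples by the sample codes in the labels.

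The table held 23067 genes and 0 values at 0, so genes at exactly 0 in any library appear to have no row. Genes at exactly 0 throughout 1 group were therefore not analysed here. The lowest value of a library was 1e-06 or 2e-06 FPKM, so levels close to 0 do occur, and the alternative with no filter tested all 23067 genes. FPKM values carry no read counts. Low values were checked for steps of whole reads, and a search of step lengths gave multiples within 0.1 of a whole number for 40.65% to 47.06% of values. With gene lengths shuffled 100 times the highest share was 26.4%, so steps are present, though most values lie off them and read counts were not recovered. The best steps within a doubling of length put the deepest library at 1.12 times the shallowest. Steps of 0.5 and 2 times these lengths also exceeded that share, so the absolute depth of each library is unknown. In all 6 libraries the share was higher at 0.5 times the length than at the length itself, so these steps were not the best over all lengths. It was 42.0% against 41.7% in wild type replicate 1 and 46.3% against 41.2% in wild type replicate 3. Precision was therefore taken from the spread between libraries. The FPKM of a library summed to between 314146 and 335508. Nothing in the labels states that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

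Values were transformed as log2(FPKM + 1), which understates the change of genes at low levels, and genes with a mean of at least 1 FPKM over the 6 libraries were tested, 14156 in all. Genotypes were compared with limma 3.58.1 in R 4.3.3, with a trended prior variance and robust estimation, two-sided, and with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Adjusted p-values of genes are from this limma model throughout. Fold changes given as FPKM ratios are ratios of group means. Confidence intervals of 95% are on the log2(FPKM + 1) scale.

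The lists of genes numbered 41, of which 40 had at least 3 tested members, the sex-linked list being the exception. They were compared with the other genes by camera of limma with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Called genes near Lrrk2 were counted within 10 Mb and compared with the rest of the genome by Fisher's exact test, two-sided.

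The genes named were Lrrk2, the 4 AMPA receptor subunits, and the largest changes among called genes. As fewer than 10 genes were called, the 5 genes with the smallest p in each direction were taken instead, without predicted gene models, and up to 4 members with the smallest p in each list described. Gm42715, Tmem265, Slc17a7, Ttr, Xist, Tsix, Chrm3, Chrm4, Rtn4r, Nptx1, Pcmtd1, Mir8112 and Cx3cr1 fall outside that rule in the places where they are named and were chosen after their values were seen, except where they are among a list's members with the smallest p. The design, the lists, the naming rule and all alternatives but those named below were fixed before the data were examined.

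Gene positions, transcript numbers and overlaps are from GENCODE release M21 on GRCm38, matched by gene identifier. Of the 23067 identifiers 22987 matched, and 22187 of these had the same symbol. It may differ from the annotation the authors used.

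The scripts were tested on simulated data with the real genes' mean levels. The spread of each gene was the limma estimate, which is drawn towards the prior variance. In a simulation of the knock-in against wild-type comparison over 14156 genes, with 200 genes changed, 73.1% of genes changed by 1.5-fold, 89.6% of those changed by 2-fold and 95.5% of those changed by 3-fold were called in the right direction, with 11 unchanged genes called. A list raised by 20% was called, and 0 of 39 other lists were. The noise was normal and held no pairs of tight levels as described below, so these shares and false calls may not hold for genes with such levels. Noise was drawn independently for each gene, so this cannot show how often lists of correlated genes are called falsely. The correlation estimated in the data was 0.80 in the list of myelinating oligodendrocytes.

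The alternatives tried were a replicate block, each replicate left out, median-of-ratios scaling, quantile normalization, no filter or a minimum mean of 5 FPKM, a pseudocount of 0.1, limma without trend and robust estimation, an added fold minimum, a threshold of 0.1, an estimated inter-gene correlation and windows of 5 and 20 Mb around Lrrk2. After the data were seen, a covariate of cortical marker level and a fit without mitochondrial genes and genes above 1000 FPKM were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.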

Results

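The dataset compared gene expression in the dorsal striatum of wild-type mice and of mice homozygous for the G2019S change in Lrrk2, a kinase altered in familial Parkinson's disease. It holds 3 libraries per genotype, all from postnatal day 21 and all titled male. Libraries correlated with each other over genes at 0.983 to 0.989 within a group and at 0.984 to 0.990 between groups. Between 13999 and 14191 genes reached 1 FPKM in a library.

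The first comparison asked which genes differed between genotypes. Chrm1, the M1 muscarinic acetylcholine receptor, rose in knock-in striatum from 6.64 ± 0.154 to 19.3 ± 0.262 FPKM (SD, n = 3 each), a 2.91-fold ratio. Mapkap1, which encodes the SIN1 subunit of the mTORC2 kinase complex, fell from 15.5 ± 0.438 to 8.05 ± 0.508 FPKM, a ratio of 0.520. The predicted gene Gm42715, whose exons overlap those of the chromatin remodeller Srcap, rose from 1.00 ± 0.177 to 4.67 ± 0.293 FPKM and was chosen after its values were seen. The levels of each of the 3 genes did not overlap between the 3 knock-in and 3 wild-type libraries, a separation that chance gives 10% of single genes. The changes on the log2 scale were 1.41 (SE 0.05, adjusted p = 0.000154) for Chrm1, -0.87 (SE 0.06, adjusted p = 0.00708) for Mapkap1 and 1.51 (SE 0.09, adjusted p = 0.00187) for Gm42715. These were the 3 genes called among 14156 tested, 2 higher and 1 lower. At an unadjusted p under 0.05, 604 genes passed, 177 higher and 427 lower, where 707.8 are expected by chance. The count was 8 without wild type replicate 2, 11 without knock-in replicate 1, 15 without knock-in replicate 2 and 6 without knock-in replicate 3, and Mapkap1 lost its call without wild type replicate 1 (adjusted p = 0.0509) or wild type replicate 3 (adjusted p = 0.0601). Mapkap1 also lost its call with a replicate block (adjusted p = 0.0581 in limma). Chrm1 and Gm42715 were called in each of these fits. All 3 called genes were among 225 genes at a pair of tight levels over the libraries, described below. Tight levels that follow the groups tend to outlast the loss of a library, so this is no separate evidence for genotype. Of the 10 splits of the libraries into 3 and 3, the real one included, 7 called as many genes.

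**Figure D1:**
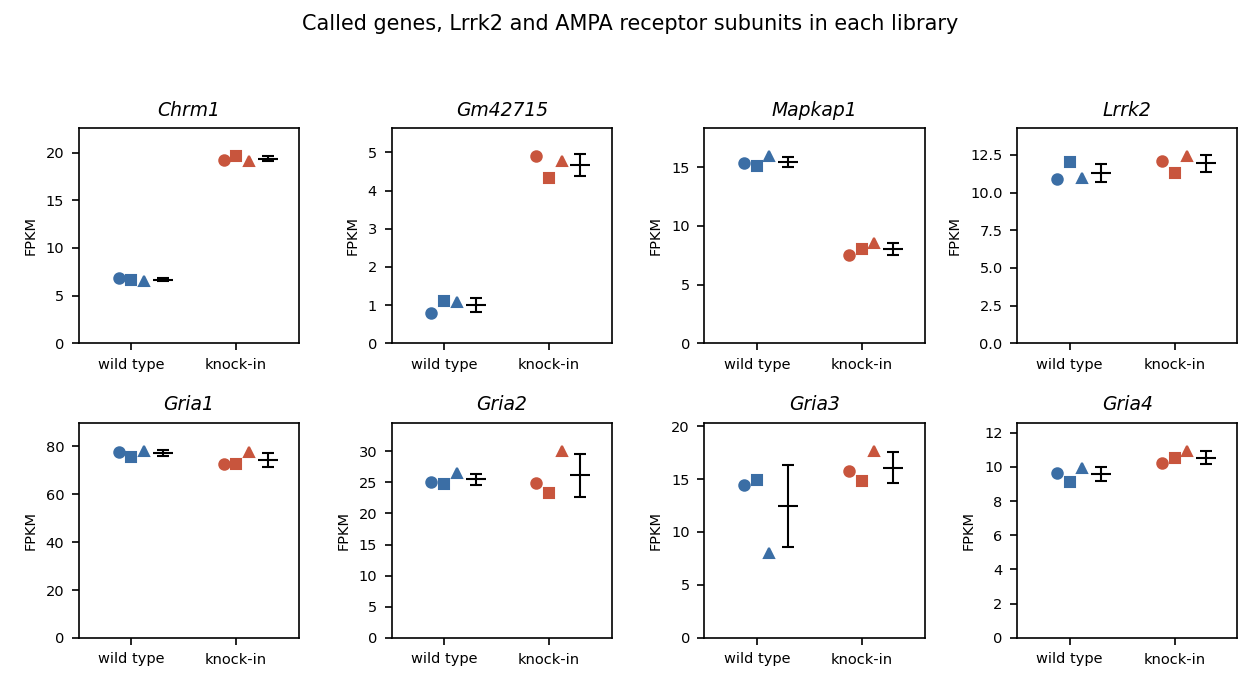
FPKM of the 3 called genes, Lrrk2 and the 4 AMPA receptor subunits in each library of wild type and knock-in, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the group mean and SD. Chrm1 lies between 6.52 and 6.82 FPKM in wild type and between 19.2 and 19.6 FPKM in knock-in. Gria1, Gria2 and Gria3 overlap between genotypes, and Gria4, which was not called, does not.

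Chrm1 (ENSMUSG00000032773) lies on chromosome 19 at 8663789 to 8683587 and has 3 annotated transcripts, and 329 of its exon bases lie opposite an RNA on the other strand. Mapkap1 (ENSMUSG00000038696) lies on chromosome 2 at 34406771 to 34624950, with 11 transcripts. Gm42715 (ENSMUSG00000107023) lies on chromosome 7 at 127519584 to 127567054 and shares 9738 exon bases with Srcap and 1263 with Tmem265 on the same strand, so that reads could be assigned to any of the 3 genes. Tmem265 stood at 3.24 ± 0.419 FPKM in wild type and 1.32 ± 1.21 FPKM in knock-in (SD, n = 3 each) and was not called with all 6 libraries. All positions are on GRCm38. Chrm4, the M4 muscarinic receptor of striatal projection neurons, was at 53.5 ± 0.407 FPKM in wild type and 53.2 ± 4.16 FPKM in knock-in (n = 3 each). Its log2 difference of -0.01 was not called. Chrm3, the M3 receptor, stood at 2.39 ± 0.283 and 3.25 ± 0.618 FPKM, on average in the direction of Chrm1, and its log2 difference of 0.32 was not called either (adjusted p = 0.997). Unlike Chrm1, it was not higher in all knock-in libraries. It was at 3.65 and 3.57 FPKM in knock-in replicates 1 and 2. In knock-in replicate 3 it was at 2.54 FPKM, within the wild-type range of 2.09 to 2.65 FPKM.

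Below the threshold, the genes next in rank are given as values. In the direction of higher in knock-in, the microRNA gene Mir3100 stood at 0.626 and 1.58 FPKM in wild type and knock-in, the adaptor gene Bicdl1 at 5.79 and 8.22 FPKM, the noncoding Sox2ot at 1.75 and 3.73 FPKM and Actr3, a subunit of the Arp2/3 actin nucleator, at 22.7 and 31.9 FPKM. In the other direction, Srcap stood at 7.53 and 3.07 FPKM, the zinc finger gene Zfp961 at 2.87 and 0.818 FPKM, Fam183b at 3.37 and 1.52 FPKM and Chmp4b, an ESCRT-III subunit, at 79.3 and 61.1 FPKM. Their adjusted p-values in limma lay between 0.336 and 0.635, so none of the 8 was called. Srcap was called without knock-in replicate 1 (log2 difference -1.27, adjusted p = 0.0264).

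The edited gene itself, Lrrk2, was measured at 11.3 ± 0.625 FPKM in wild type and 11.9 ± 0.579 FPKM in knock-in (SD, n = 3 each). The log2 difference was 0.07 (SE 0.07, adjusted p = 0.997), with a 95% interval of the fold from 0.947 to 1.17. Lrrk2 lies on chromosome 15 at 91673175 to 91816120. A point change leaves the transcript in place, so this level does not check the labels.

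The series is concerned with AMPA receptors, the main fast glutamate receptors, so their subunits were compared next. Gria1 was at 77.1 ± 1.30 FPKM in wild type and 74.3 ± 2.95 FPKM in knock-in, and Gria2 at 25.4 ± 0.960 and 26.1 ± 3.52 FPKM (SD, n = 3 each). Gria3 was at 12.5 ± 3.86 and 16.1 ± 1.46 FPKM, and Gria4 at 9.56 ± 0.404 and 10.5 ± 0.369 FPKM. In wild type replicate 3 Gria3 was at 8.01 FPKM, against 14.5 to 17.7 FPKM in the other libraries. Gria4 did not overlap between genotypes, at 9.13 to 9.93 FPKM in wild type and 10.2 to 10.9 FPKM in knock-in. Chance gives such a separation to a share of 0.1 of single genes. The log2 differences were -0.05, 0.03, 0.39 and 0.13 for Gria1 to Gria4, each with an adjusted p of 0.997 in limma, and 0 of the 4 were called over all genes or adjusted over the list alone, 0 also at an unadjusted p under 0.05. The 95% intervals of the fold were 0.876 to 1.06 for Gria1, 0.874 to 1.19 for Gria2, 0.892 to 1.91 for Gria3 and 0.993 to 1.203 for Gria4, so a larger difference in Gria3 would have gone undetected. Without wild type replicate 3 the Gria3 difference was 0.12, and without knock-in replicate 3 the Gria2 difference turned to -0.07.

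The proteins that traffic and anchor these receptors were also compared by list. Of 38 measured auxiliary and trafficking genes, 21 were higher and 17 lower, and 0 were called. Nptx2, a pentraxin that clusters AMPA receptors, stood at 8.12 ± 0.488 and 9.74 ± 1.33 FPKM in wild type and knock-in, and the auxiliary subunit gene Cacng3 at 35.0 ± 4.06 and 40.8 ± 4.66 FPKM (SD, n = 3 each). In knock-in replicate 3 both lay within their wild-type ranges. Nptx2 was at 8.20 FPKM there, against 7.57 to 8.48 FPKM in wild type, and Cacng3 at 36.2 FPKM, against 30.6 to 38.6 FPKM. The list as a whole was not called (adjusted p = 0.239 in camera), nor was that of the 4 subunits (adjusted p = 0.185). With the cortical marker level as a covariate, an alternative chosen after the data were seen, the list of subunits was called as higher (adjusted p = 0.0405). NMDA, kainate and metabotropic glutamate receptors (19 genes, adjusted p = 0.565), postsynaptic scaffolds (30 genes, adjusted p = 0.295) and GABA synthesis and receptors (22 genes, adjusted p = 0.185) were not called, and were called in 1, 1 and 2 of 15 alternatives. Among the scaffolds Homer1 stood at 12.2 ± 0.888 and 15.5 ± 1.58 FPKM (adjusted p = 0.219 over the list alone).

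The gene lists gave 10 calls out of 40 with the preset correlation, 5 higher and 5 lower in knock-in. With an estimated correlation 0 lists were called, each with an adjusted p of at least 0.847 and 2 with an unadjusted p under 0.05, and fry, which tests whether a list moves on balance 1 way, called 0. Without knock-in replicate 2 the count was 16. Genes of ependyma and ciliated cells were lower, with 11 of 11 measured genes lower and a median log2 difference of -0.36 (adjusted p = 1.39e-09 in camera, adjusted p = 0.847 with an estimated correlation). The median over members relative to the wild-type mean was -0.46 and -0.40 in knock-in replicates 1 and 3 and -0.13 in knock-in replicate 2, against -0.06 to 0.06 in the wild-type libraries. Of these, 7 were called adjusted over the list alone and 0 over all genes, among them the radial spoke gene Rsph1, at 5.26 ± 0.227 FPKM in wild type and 3.70 ± 0.410 FPKM in knock-in, and the adenylate kinase gene Ak7, at 2.22 ± 0.162 and 1.502 ± 0.197 FPKM (SD, n = 3 each).

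Lists of the oligodendrocyte lineage were lower too. Of 20 genes of myelinating oligodendrocytes, 19 were lower, with a median of -0.19 (adjusted p = 1.38e-08 in camera), and 14 of 14 genes of oligodendrocyte precursors were lower, with a median of -0.19 (adjusted p = 2.74e-07, and adjusted p = 0.847 with an estimated correlation for both). Ugt8a, which makes the myelin lipid galactocerebroside, stood at 52.5 ± 2.59 and 44.3 ± 3.73 FPKM in wild type and knock-in, and the precursor receptor gene Gpr17 at 38.6 ± 1.04 and 30.5 ± 5.81 FPKM (SD, n = 3 each). 0 members of either list were called, adjusted over the list alone or over all genes. Knock-in replicate 3 stood apart in both lists, with a median over members of -0.38 for myelinating oligodendrocytes and -0.36 for precursors relative to the wild-type mean, against -0.14 and -0.17 in knock-in replicate 1 and -0.09 and -0.07 in knock-in replicate 2. The wild-type libraries ranged from -0.11 to 0.08 and from -0.02 to 0.04, so for myelinating oligodendrocytes the genotypes overlapped. In the same library blood genes were at -0.81, immediate early genes at -0.28 and astrocyte and microglia genes at -0.17 each. Without that library the median of myelinating oligodendrocytes was -0.11, still called (adjusted p = 0.000283), and with the cortical covariate it was -0.30. Subventricular neuroblasts and dividing cells were lower in 9 of 13 genes, with a median of -0.22 (adjusted p = 0.00133 in camera), where Igfbpl1 stood at 2.21 ± 0.210 and 1.39 ± 0.322 FPKM. This call was lost without wild type replicate 3 (adjusted p = 0.0574) and at a minimum mean of 5 FPKM, where the median turned to 0.02 (adjusted p = 0.664). The choroid plexus list had 3 measured genes, all lower (adjusted p = 0.0150 in camera), and its call was lost without wild type replicate 2 (median -0.15, adjusted p = 0.0953), without knock-in replicate 3 (median -0.22, adjusted p = 0.127) and with the cortical covariate (median -0.35, adjusted p = 0.1004), against a median of -0.30 in the comparison as designed. Ttr, the plexus transthyretin, was at 374 FPKM in wild type replicate 2 against 2.12 to 16.2 FPKM in the other 5 libraries. Both lists lost their calls with an estimated correlation (adjusted p = 0.847).

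**Figure D2:**
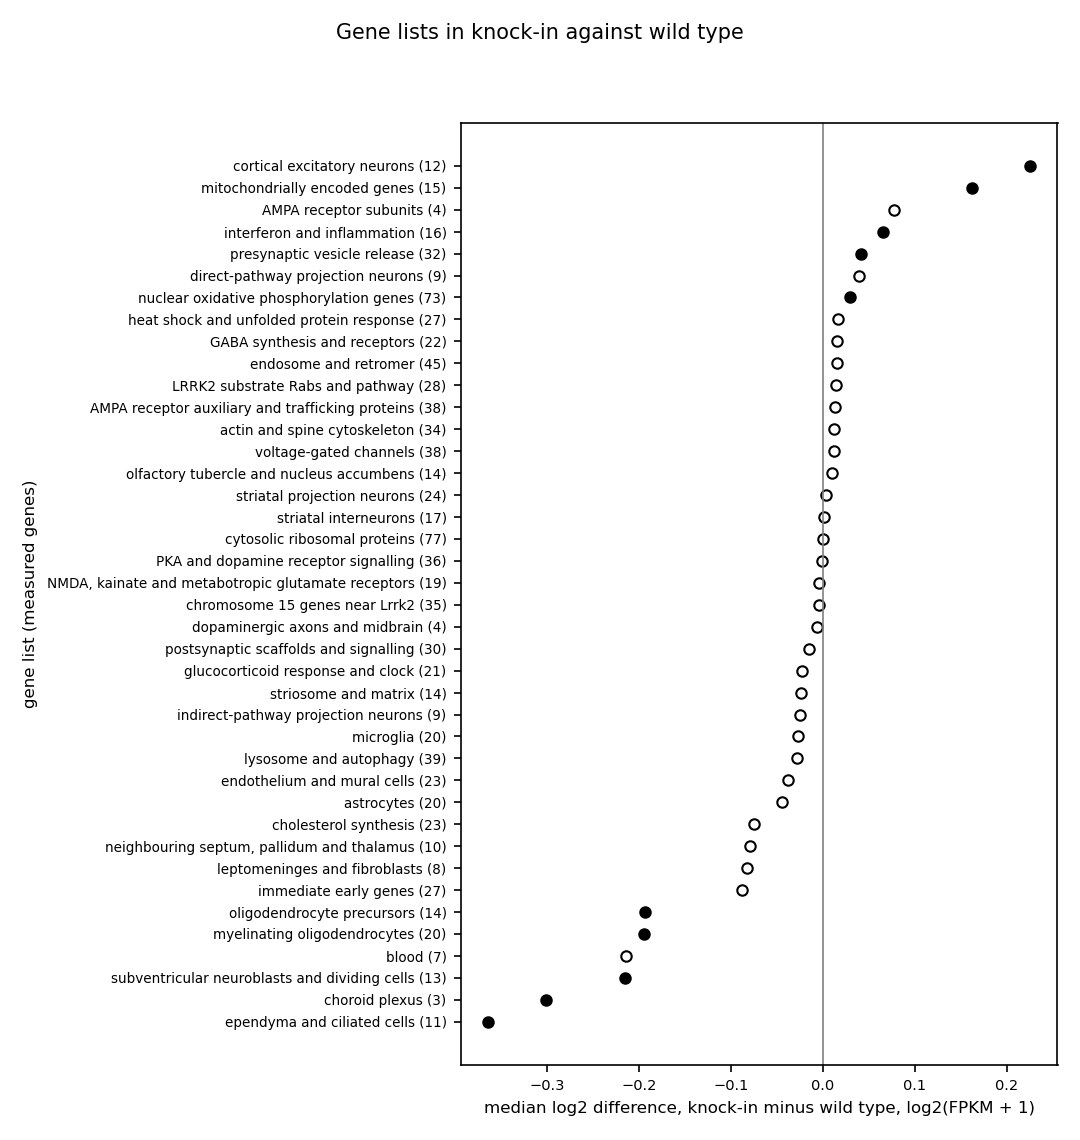
Median log2 difference between knock-in and wild type of each of the 40 gene lists, with the number of measured genes in parentheses. Filled points are the 10 lists called with a preset correlation, of which 0 were called with an estimated one, and they run from -0.36 for ependyma and ciliated cells to 0.23 for cortical excitatory neurons.

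Among lists that were higher, the 15 mitochondrially encoded genes were all higher, with a median of 0.16 (adjusted p = 1.22e-05 in camera), and mt-Nd3, a subunit of complex I, stood at 598 ± 37.2 FPKM in wild type and 844 ± 158 FPKM in knock-in (SD, n = 3 each). Mitochondrial genes took 23.2% of summed FPKM in knock-in replicate 3 and 18.0% to 20.5% in the other libraries, and the list lost its call without that library (median 0.05, adjusted p = 0.128) and with quantile normalization (median 0.0026, adjusted p = 0.237). The median was 0.25 without knock-in replicate 2 and 0.26 with the cortical covariate. Cortical excitatory neuron genes were higher in 11 of 12 measured genes, with a median of 0.23 (adjusted p = 0.000717 in camera). Slc17a7, the vesicular glutamate transporter of cortical neurons, was at 29.9 and 25.2 FPKM in knock-in replicates 1 and 2, at 11.0 FPKM in wild type replicate 1 and at 2.73 to 3.55 FPKM in the other libraries. The call of this list was lost without knock-in replicate 1 (adjusted p = 0.270) or knock-in replicate 2 (adjusted p = 0.103), where the median was 0.05 in each case. It was also lost with the cortical covariate (adjusted p = 0.544 in camera), but that covariate is the mean of this same list, so the loss was built in. The median was 0.38 without wild type replicate 1, 0.64 without knock-in replicate 3 and 0.09 at a minimum mean of 5 FPKM. Both lists lost their calls with an estimated correlation (adjusted p = 0.847).

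**Figure D3:**
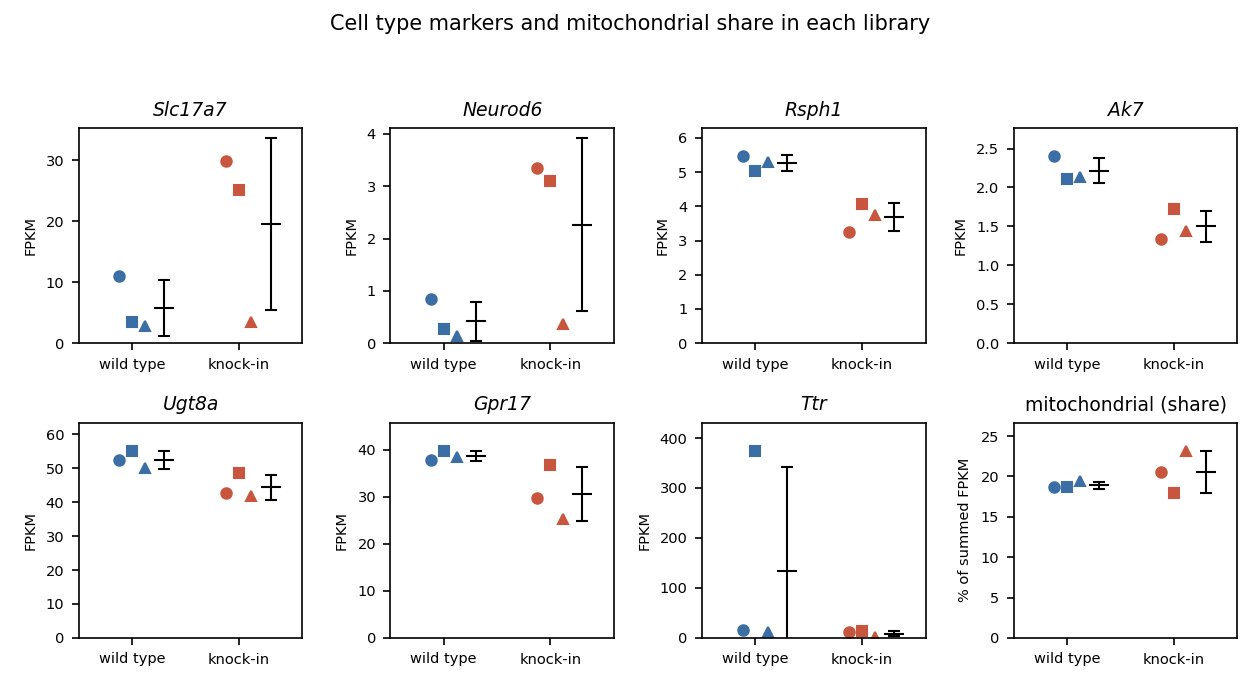
FPKM of cortical (Slc17a7, Neurod6), ciliated (Rsph1, Ak7), oligodendrocyte lineage (Ugt8a, Gpr17) and choroid plexus (Ttr) genes and the percentage of summed FPKM from mitochondrial genes in each library, with symbols for replicates and bars for group mean and SD, cut at 0. Slc17a7 is highest in knock-in replicates 1 and 2, at 29.9 and 25.2 FPKM, and Ttr in wild type replicate 2, at 374 FPKM.

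Presynaptic vesicle release genes were higher in 23 of 32, with a median of 0.04 (adjusted p = 0.0362 in camera), a list that holds Slc17a7, and Snap25, a SNARE of vesicle fusion, stood at 92.2 ± 4.35 and 110 ± 11.5 FPKM (SD, n = 3 each). The call was lost in 8 of 16 alternatives. These were the fits without wild type replicate 1 (adjusted p = 0.126), wild type replicate 3 (adjusted p = 0.0959) or knock-in replicate 1 (adjusted p = 0.722), quantile normalization (adjusted p = 0.207), no filter (adjusted p = 0.0693), a minimum of 5 FPKM (adjusted p = 0.0893), the cortical covariate (adjusted p = 0.544) and the estimated correlation (adjusted p = 0.847). The median was 0.016 without wild type replicate 1, -0.0048 without knock-in replicate 1, 0.02 without knock-in replicate 2, 0.08 without knock-in replicate 3 and -0.03 with the covariate.

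Nuclear oxidative phosphorylation genes were higher in 56 of 73, with a median of 0.03 (adjusted p = 0.00301 in camera). Knock-in replicate 2 stood apart, with a median over members of 0.18 relative to the wild-type mean, against -0.02 and -0.09 in knock-in replicates 1 and 3 and -0.05 to 0.07 in wild type. In the same library ribosomal protein genes were at 0.19 and heat shock and unfolded protein response genes at 0.14. The list turned lower, and was not called, without knock-in replicate 2 (median -0.05, adjusted p = 0.152) and with the cortical covariate (median -0.06, adjusted p = 0.279). Its call was also lost without wild type replicate 2 (median 0.011, adjusted p = 0.0953) or wild type replicate 3 (median 0.018, adjusted p = 0.103), with quantile normalization (adjusted p = 0.0540) and with an estimated correlation (adjusted p = 0.847). The median was 0.07 without wild type replicate 1, 0.06 without knock-in replicate 1, 0.09 without knock-in replicate 3 and 0.05 with median-of-ratios scaling.

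Interferon and inflammation genes were higher in 13 of 16, with a median of 0.07 (adjusted p = 0.0050 in camera), and 3 passed adjusted over the list alone, Ifit3 at 1.98 ± 0.143 and 2.56 ± 0.0565 FPKM, Ifitm3 at 12.5 ± 1.18 and 15.6 ± 1.16 FPKM and, in the other direction, the complement gene C4b at 5.195 ± 0.12 and 4.20 ± 0.201 FPKM (SD, n = 3 each). The call was lost without wild type replicate 1 (adjusted p = 0.0622), wild type replicate 3 (median 0.018, adjusted p = 0.0959) or knock-in replicate 2 (median 0.04, adjusted p = 0.0504). It was also lost at a minimum of 5 FPKM (median 0.10, adjusted p = 0.0513), with the cortical covariate (median 0.013, adjusted p = 0.161) and with an estimated correlation (adjusted p = 0.847). The median was 0.16 without wild type replicate 2 and 0.14 without knock-in replicate 3.

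The other called lists had the following levels per library. Relative to the wild-type mean, the medians over members in knock-in replicates 1, 2 and 3 were 0.14, -0.04 and 0.37 for mitochondrially encoded genes, against -0.05 to 0.04 in wild type, and 0.48, 0.38 and -0.14 for cortical excitatory neurons, against -0.16 to 0.28. They were 0.12, 0.02 and -0.05 for presynaptic vesicle release, against -0.01 to 0.01, and 0.11, 0.16 and -0.03 for interferon and inflammation, against -0.05 to 0.09. For neuroblasts and dividing cells they were -0.13, -0.09 and -0.26, against -0.08 to 0.08, and for the choroid plexus -0.32, -0.19 and -0.46, against -0.25 to 0.39.

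Lists of striatal neurons were not called in the comparison as designed. Genes of direct-pathway projection neurons (9 genes, adjusted p = 0.565), indirect-pathway projection neurons (9 genes, adjusted p = 0.834), shared projection neuron markers (24 genes, adjusted p = 0.244) and interneurons (17 genes, adjusted p = 0.657) were not called. Penk, the enkephalin precursor of indirect-pathway neurons, was at 1057 ± 49.7 and 1118 ± 67.2 FPKM, and Tac1, the substance P precursor of direct-pathway neurons, at 45.3 ± 4.32 and 51.8 ± 10.4 FPKM (SD, n = 3 each). Substrate Rabs and partners of LRRK2 (28 genes, adjusted p = 0.295) were not called, nor were PKA and dopamine receptor signalling (36 genes, adjusted p = 0.175), which holds Chrm1 as its 1 called member and was the 1 list called by fry for change in either direction, a test that does not compare lists. Of 15 alternatives with the preset correlation, 3 called shared projection neuron markers, 3 called PKA and dopamine receptor signalling and 1 called direct-pathway neurons, while 0 called interneurons, indirect-pathway neurons or the LRRK2 list.

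The remaining lists were not called in the comparison as designed, with their adjusted p in camera as follows. Among cell types, astrocytes were at 0.239, microglia at 0.937, endothelium and mural cells at 0.413, leptomeninges and fibroblasts at 0.333, and blood at 0.175. Striosome and matrix genes were at 0.937, neighbouring septum, pallidum and thalamus at 0.413, olfactory tubercle and accumbens at 0.835 and dopaminergic axons and midbrain at 0.657. Immediate early genes were at 0.144, cholesterol synthesis at 0.113, voltage-gated channels at 0.382, lysosome and autophagy at 0.8805, endosome and retromer at 0.834, actin and spine cytoskeleton at 0.349, ribosomal proteins at 0.464, heat shock and unfolded protein response at 0.175, and glucocorticoid response and clock at 0.690. Some of these were called under part of the 15 alternatives, cholesterol synthesis in 5, immediate early genes and ribosomal proteins in 4 each, blood in 3, astrocytes and voltage-gated channels in 2 each, and heat shock and unfolded protein response in 1. The sign of the median, the mean and the test disagreed in lists that were not called, namely PKA and dopamine signalling, postsynaptic scaffolds, NMDA and other glutamate receptors, dopaminergic axons, microglia, ribosomal proteins, interneurons, indirect-pathway neurons, endosome and retromer, and olfactory tubercle and accumbens. Adjusted over the list alone, Chmp4b passed in the endosome list (adjusted p = 0.0252 in limma) and Actr3 in the actin list (adjusted p = 0.00936 in limma).

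A knock-in line can carry donor sequence around the edited gene, so called genes near Lrrk2 were counted. Of the 3 called genes 0 lay within 10 Mb of Lrrk2, where 196 of the 14156 tested genes lie (Fisher's exact p = 1.00). With so few called genes and so small a window, 0 was the likely count in any case. This test therefore cannot speak for or against donor sequence there. At an unadjusted p under 0.05, 3.57% of genes in the window passed and 4.28% elsewhere (Fisher's exact p = 0.858). The list of 35 measured genes near Lrrk2 was not called (adjusted p = 0.657 in camera), and its members Senp1 and Syt10 stood at 1.53 ± 0.0993 and 1.14 ± 0.147 FPKM and at 1.82 ± 0.0978 and 1.51 ± 0.1004 FPKM in wild type and knock-in (SD, n = 3 each).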

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

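The cortical covariate and the fit without mitochondrial and very abundant genes were chosen after the data were seen. The count of called genes was 3 and ranged from 2 to 15 over 17 alternatives, 13 of them within 1.5 times. Lrrk2 was not called in 15 of 15 alternatives, 0 of the AMPA subunits were called in any, and 0 called genes lay near Lrrk2 in 17. With so few called genes, the last of these counts cannot speak for or against donor sequence near Lrrk2. Leaving out 1 replicate gave 3 to 15 called genes, 2 to 6 higher and 0 to 9 lower, and 7 to 16 lists. Of 30 genes gained in these fits, 27 were at a pair of tight levels over the 6 libraries, and the library left out was the 1 that kept them from following genotype. The other 3 were Srcap, Pcmtd1 and Mir8112, the latter not tested with all libraries. The cause of the change in lists was not tested. With a replicate block, 2 genes were called, 2 higher and 0 lower, and 11 lists. Mapkap1 then had an adjusted p of 0.0581. Deviations from the group mean correlated at -0.01, -0.07 and 0.19 between samples with the same number, and wild type 1 correlated best with knock-in 2, at 0.21. These values give no clear sign that the numbers pair the samples. Such deviations cancel out within a group for each gene, so the values depend on each other, and with 3 samples per group they cannot exclude a pairing. A minimum of 5 FPKM gave 1 higher gene, since Gm42715 was then not tested, and 5 lists. The cortical covariate gave 17 lists and an estimated inter-gene correlation 0. The median of nuclear oxidative phosphorylation genes turned to -0.056 with the cortical covariate and ranged from -0.047 to 0.0895 with 1 replicate left out, and that of Gria2 from -0.0748 to 0.102. The cause was not tested. The absolute depth is unknown, so it could not be used to set a limit for genes at low levels.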

Other observations

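All tests in this part were chosen after the result was seen, except the count of gene lists over other splits of the samples.

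Some genes differed in level between libraries of the same genotype. The fractalkine receptor gene Cx3cr1 was at 8.002 and 8.11 FPKM in knock-in replicates 1 and 3 and at 2.70 to 3.58 FPKM elsewhere, and Rab43 was at 0.449 FPKM in wild type replicate 1 and at 3.90 to 5.60 FPKM elsewhere. In all, 225 of 14156 tested genes lay at a pair of tight levels, with a gap of at least 1.5-fold that was over 3 times the spread within each level. Of these, 120 had 1 library apart, 80 had 2 apart and 25 were split 3 to 3.

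The 3 called genes, Chrm1, Mapkap1 and Gm42715, were among these 225 genes. The genotype split held 3 of the 25, and the 9 other splits into 3 and 3 held 0 to 4, so a pair of levels that arises whatever the genotype may account for their number. Such genes had several annotated transcripts in 92.9% of cases against 79.5% of other tested genes (Fisher's exact p = 5.71e-08), and shared exons with a gene on the same strand in 20% against 8.90% (Fisher's exact p = 4.25e-07), where genes are not independent. Cortical tissue is argued against, since with the cortical covariate the 3 genes kept at least 94.1% of their log2 change. The 5 cortical markers kept -20% (Nptx1) to 33.8% (Rtn4r). They belong to the list averaged into the covariate, so their loss was built in and does not show that the covariate works. An effect of genotype stays open, and over the 10 splits of the samples, too few for a share under 0.05, the real one called 3 genes and the highest other 6, with 7 splits calling as many. The real split called 10 lists and the highest other 15, with 6 splits calling as many.

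Gm42715 and Srcap lie on the same strand of chromosome 7 with 9738 shared exon bases, and differed in opposite directions, Gm42715 from 1.00 to 4.67 FPKM and Srcap from 7.53 to 3.07 FPKM, the latter called only without knock-in replicate 1. A candidate explanation is that reads were divided differently between the overlapping models. The test chosen for it was the sum of both weighted by exon length, whose log2 difference of -0.30 exceeded the larger group SD of 0.25. The weighted sums overlapped between genotypes, at 4.22 in wild type replicate 1 and 4.46 in knock-in replicate 1. With 3 libraries per group, a difference of about the SD cannot decide the question. The unweighted sum differed by -0.15, within its SD of 0.23. FPKM is scaled for length, and the exons of Srcap and Gm42715 span 15783 and 12746 bases. An unweighted sum is therefore not kept when reads move between these genes, and it cannot decide the question. With Tmem265, which shares 1263 exon bases with Gm42715, the weighted sum differed by -0.32 against an SD of 0.23. The unweighted sum, with the same limit, differed by -0.38 against 0.09. Tmem265 itself was at 0.515, 2.72 and 0.741 FPKM in knock-in replicates 1, 2 and 3, against 2.77 to 3.57 FPKM in wild type. It was called without knock-in replicate 2. The weighted sums overlapped again, at 4.18 in wild type replicate 1 and 4.30 in knock-in replicate 1, while the unweighted sums did not overlap. A different division of reads and a change with genotype both stay open.

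Xist, the noncoding RNA of the inactive X chromosome, was at 27.2 to 39.3 FPKM in all 6 libraries, although their titles give male animals. A candidate explanation is that the animals were female, which the lowest level of 27.2 FPKM fits, and 0 of the 4 Y-linked genes of the list had a row in the table. Why these rows are missing was not established, so their absence decides nothing alone. Reads of the antisense gene Tsix counted as Xist are argued against, since Tsix has 4097 exon bases outside those of Xist and its row allows at most 0.197 FPKM on them. The level was 32.0 ± 0.890 FPKM in wild type and 32.4 ± 6.20 FPKM in knock-in (SD, n = 3 each).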
